A study of Homo sapiens with 14 samples.

How the data were processed

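Gene expression was profiled in 5 squamous cell lines after transfection with Fugene 6 of a control vector or a vector expressing p63 siRNA, per the labels. Hygromycin B selection began 48 h after transfection, and 300 ng of mRNA was labelled by in vitro transcription. SCC-012 cells were grown in RPMI and the other lines in DMEM, per the labels' protocols, so medium and line cannot be separated, but each ratio was taken within a line. The deposited values are linear signal intensity per probe set, 1 column per array, made by the authors with MAS5 per the submitters' processing notes; its version is not given in the sources used here. The 2% trimmed mean of the deposited intensity lay between 500.04 and 500.17 on all 14 arrays, which is a global scaling to 500. Detection calls were not used here, and 0 columns of per-sample values were left unused. HG133 Plus 2.0 arrays held 54675 probe sets, HG133A 22283 and HG133B 22645. MAS5 signals of dim probe sets are noisy and have no replicate here, and global scaling would hide a shift of most genes in 1 direction.

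Samples were grouped by the cell line and vector in the labels. The numbers 1 and 2 in the titles of HaCaT RG and SCC-1 mark the HG133A and the HG133B array, so they are not replicates; the labels do not say whether both arrays received the same RNA. Control and siRNA samples were paired because they come from the same cell line. Each line has 1 sample per vector, so the lines are the replicates, 2 of the 5 are HaCaT, and the p-values describe the spread between these lines. Array type is nested in cell line, and the pairing removes a constant shift of a gene's log2 signal between array types. It does not remove how the floor, the filter and the choice of probe set act on each array type. Each array was scaled by itself, and the median deposited signal was 237 to 245.8 on HG133B and 150.6 to 200 on Plus 2.0.

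Each array was rescaled to a 2% trimmed mean of 500, values under 50 were set to 50 and log2 was taken. The 44692 probe sets shared by Plus 2.0 and HG133A or HG133B were used, 22215 read from A and 22477 from B. Probe sets were named through the platform annotation, in which 34408 of them had 1 gene symbol, 1583 had several and 8701 were not listed; those with several named no gene. A check through Entrez identifiers matched 34371 and changed 0 symbols. Of 17518 genes the probe set with the highest mean signal over the 10 samples was kept, and the 14144 genes with a mean signal of at least 100 were tested. No coordinates are given, since no genome build is named in the sources used here. The targeted gene is not reported here.

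Genes were tested with limma 3.58.1 in R 4.3.3, with cell line as a block and 4 residual degrees of freedom, eBayes with an intensity trend and Benjamini-Hochberg adjustment at 0.05. A count of genes moved at least 1.5-fold the same way in all 5 lines was set against the 16 patterns of signs of the within-line ratios. The difference between the 3 SCC lines and the 2 HaCaT lines was tested with limma on the 5 ratios. Within a line, and for correlations across genes, values are given without a test. Before the data were examined, 22 gene lists were written with 706 entries (660 genes, of which 549 were tested): basal keratins, hemidesmosome, desmosome, cornified envelope, reported p63 targets, mesenchymal, neural, invasion, p53 targets, cell cycle, interferon, immediate early, Notch, EGF receptor, inflammatory cytokines, cholesterol, hypoxia, leukocytes, endothelial cells, melanocytes, simple epithelium and housekeeping. They were tested with camera with a preset correlation of 0.01, with an estimated correlation, and with fry. A list's median within a line was placed among 10000 random lists matched on mean signal.

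The genes named were chosen by a rule fixed before the data were examined. It took up to 10 genes per direction that passed in limma with 1 direction in all lines, filled up from genes moved 1.5-fold in all lines; per list, up to 4 members with the smallest p and up to 4 moved 1.5-fold in all lines; per direction 5 genes without overlap between HaCaT and SCC; and per line the 3 highest and 3 lowest ratios among genes with a signal of at least 500. The text gives a selection of these.

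The procedure was tested on simulated data made from the 14144 genes, with 5 simulations. For genes changed across cell lines limma called 35.6% of those changed 1.5-fold, 64% of those changed 2-fold, 92.8% at 4-fold and 98% at 8-fold, with 26 calls among unchanged genes in all. For the HaCaT and SCC comparison it called 52.1% of genes with a 4-fold difference. These shares hold for many planted changes, 250 genes per fold over the 5 simulations and 1000 genes for HaCaT and SCC. More calls make the adjusted threshold easier to pass. In the real data limma called 6 genes across lines and 0 between HaCaT and SCC, so the shares found there can be lower. A list of 21 genes, all shifted by log2 0.5, was found in 5 of 5 simulations by camera with the preset correlation. The simulated noise was independent between genes, so this does not test lists whose members are correlated. Alternatives tried were other floors, filters and scalings, all probe sets averaged or tested singly, eBayes without trend or robust, no block, the HaCaT lines averaged, subsets of lines and leaving out each line.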

Results

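Gene expression was measured with Affymetrix arrays in 5 human squamous cell lines, each transfected with a hygromycin-selectable vector that expressed an siRNA against p63 or with a control vector. p63 is a transcription factor of the p53 family that maintains stratified epithelia. HaCaT is a spontaneously immortalised, non-tumorigenic human keratinocyte line, and HaCaT RG is a variant of it that the labels describe as rapidly growing. SCC-1, per the labels, is a head and neck squamous cell carcinoma line, and SCC-012 and SCC-6 carry the SCC name as well. The series held 14 arrays from 10 samples, with 1 control and 1 p63 siRNA sample per line. HaCaT, SCC-012 and SCC-6 were each read on 1 HG133 Plus 2.0 array per sample, and HaCaT RG and SCC-1 on an HG133A and an HG133B array per sample. The median deposited signal lay between 150.6 and 245.8 on the 14 arrays, and their number limits the precision. The level of the targeted gene itself was not analysed here, so the direction of each comparison rests on the labels.

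The first comparison asked which genes differed between p63 siRNA and control vector across the 5 lines. LINC01503, a long non-coding RNA gene, fell in all 5 lines by a mean log2 ratio of -3.45 ± 0.19 (limma's moderated SE, n = 5 lines), to 0.0916 times the control level. Each SE in the text is moderated in this way, so it draws on the spread of other genes too. The SD of the 5 ratios was 0.50 for LINC01503 and 0.75 for CSTA. IL1A, which encodes the cytokine interleukin-1 alpha, fell with a mean log2 ratio of -1.61 ± 0.12 (SE, n = 5). CSTA, which encodes the cornified envelope protein cystatin A, fell by a mean of -1.83 ± 0.23, S100P, a calcium-binding protein gene, by -0.95 ± 0.10, and SAT1, the polyamine acetyltransferase gene, by -0.77 ± 0.09. L1CAM, which encodes a neural cell adhesion molecule, rose 2.95-fold (log2 1.56 ± 0.16), from 1634 to 5840 signal units in HaCaT and from 162 to 323 in SCC-012.

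These 6 genes, 1 higher and 5 lower, were the ones with an adjusted p under 0.05 in limma among 14144 genes tested. The adjusted p by limma was 0.00020 for LINC01503, 0.0017 for IL1A, 0.013 for L1CAM and S100P, 0.018 for SAT1 and 0.040 for CSTA, and each of the 6 had the same direction in 5 of 5 lines. At an unadjusted p under 0.05 limma gave 1745 genes, 779 higher and 966 lower, where 707.2 would be expected without any effect. Without HaCaT, without HaCaT RG or without SCC-6 the count was 2, and without SCC-1 it was 3, while LINC01503 and IL1A were called in each of these fits. Only LINC01503 and IL1A were called with the 2 HaCaT lines averaged (n = 4), and likewise with eBayes without trend. With the HaCaT lines averaged the limma adjusted p was 0.061 for L1CAM, 0.054 for S100P and SAT1 and 0.13 for CSTA. With no filter on dim genes limma called 0 genes (1820 at an unadjusted p under 0.05), and without the pairing of samples by cell line as a block it called 0 (51 at an unadjusted p under 0.05).

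In each line LINC01503 went from a control signal of 450 to 4073 down to between 63 and 244. Its control signal was 4073 in HaCaT RG and 2572 in SCC-1, the A and B lines, and 450 to 1193 in the Plus 2.0 lines. These signals come from arrays scaled apart. Its mean log2 ratio was -3.94 in the A and B lines and -3.12 in the Plus 2.0 lines. IL1A went from 7927 to 2799 in SCC-1 and from 281 to 84 in SCC-012. CSTA had log2 ratios between -2.36 and -2.02 in HaCaT, HaCaT RG, SCC-1 and SCC-6 and -0.52 in SCC-012. The other, dimmer probe set of IL1A had a mean log2 ratio of -0.28 and that of L1CAM 1.03, and the 2 others of SAT1 had a median of -0.94. With the mean of all probe sets IL1A had a log2 ratio of -0.94, and IL1A, L1CAM, SAT1 and CSTA did not pass, with adjusted p by limma of 0.068, 0.15, 0.13 and 0.11. CSTA has 1 probe set and kept its ratio of -1.83, and that of SAT1 went from -0.77 to -0.88. For CSTA and SAT1 the lost call thus does not come from a smaller ratio.

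**Figure D1:**
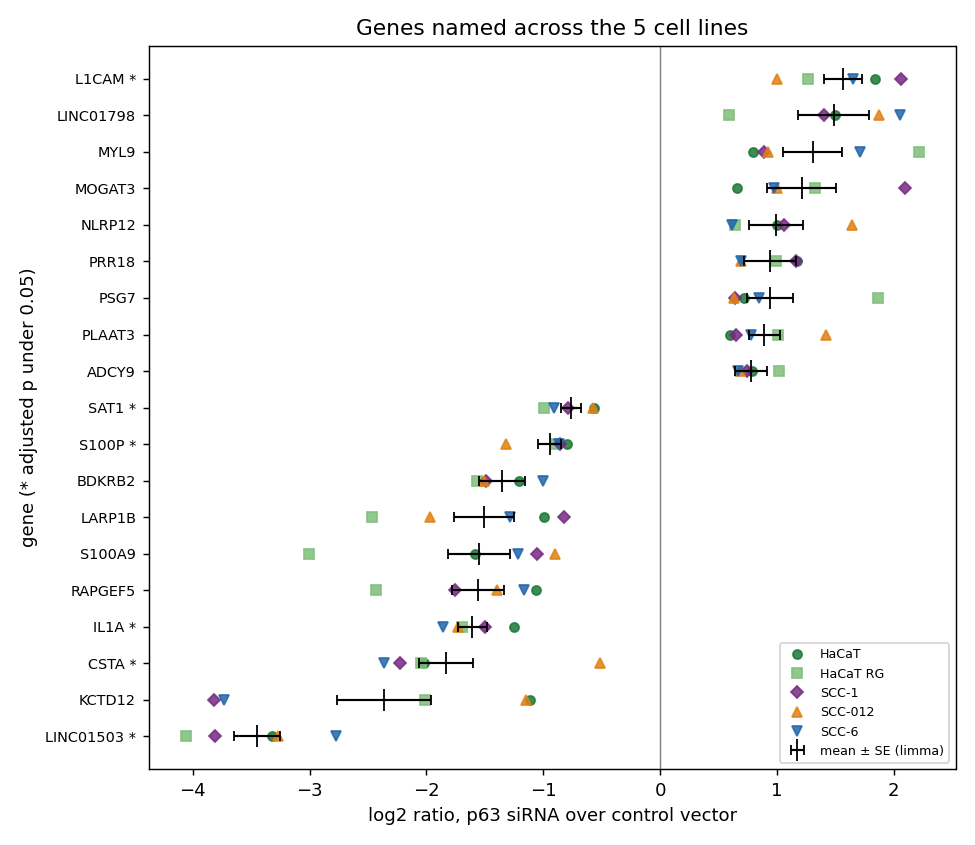
Log2 ratio of p63 siRNA over control vector (horizontal axis) for 19 genes (vertical axis), with 1 symbol per cell line and a black mark and bar for the limma mean and moderated SE over 5 lines. Stars mark the 6 genes with an adjusted p under 0.05, and LINC01503 lies lowest, with ratios from -4.06 to -2.78.

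Beyond the test, 22 genes moved at least 1.5-fold in the same direction in all 5 lines, 9 higher and 13 lower. With the medians set equal 5 were higher and 18 lower, with quantile normalization 6 and 15, with the mean of all probe sets 4 and 14, and with a floor of 100 3 and 9. Sets of fewer ratios went either way, with 64 higher and 40 lower in the Plus 2.0 lines, 25 and 22 without HaCaT and 26 and 21 without SCC-1. In the A and B lines 258 were higher and 306 lower, without HaCaT RG 17 and 22, without SCC-012 21 and 32, and without SCC-6 14 and 24. With the HaCaT lines averaged it was 19 and 19, so the balance of directions depends on these choices. The higher ones that did not pass limma's threshold included MYL9, a myosin light chain gene of contractile cells (log2 1.31 ± 0.25, adjusted p = 0.10 by limma), PLAAT3, a phospholipase gene (log2 0.89 ± 0.13), and ADCY9, an adenylyl cyclase gene (log2 0.78 ± 0.14). LINC01798, MOGAT3, NLRP12, PRR18 and PSG7 made up the rest, with mean log2 ratios from 0.94 to 1.48. PSG7 belongs to a family of near-identical pregnancy-specific glycoprotein genes, so its value is uncertain. Among the lower ones that did not pass were KCTD12 (log2 -2.36 ± 0.40), RAPGEF5 (-1.56 ± 0.22), S100A9, a calcium-binding protein gene of keratinocytes and myeloid cells (-1.55 ± 0.27), LARP1B (-1.51 ± 0.26) and BDKRB2, the bradykinin B2 receptor gene (-1.35 ± 0.20). The siRNA signal lay at the floor in 1 line each for KCTD12, S100A9 and LARP1B, so the size of their drop there is a lower bound. For LARP1B, 0 of the 4 other probe sets had the same sign. With a signal floor of 100 in place of 50 the count was 12, and the control signal of LINC01798 lay at the floor in 3 lines and those of MYL9, MOGAT3, NLRP12 and PRR18 in 2, so the size of their ratios depends on the floor. At 100 the mean log2 ratio was 0.65 for LINC01798, 0.92 for MYL9, 0.57 for MOGAT3, 0.59 for NLRP12 and 0.60 for PRR18.

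The next question was whether groups of genes with a known role shifted together. Inflammatory cytokines and chemokines were shifted down, with a mean log2 ratio of -0.48 over 24 measured members. IL1A fell, and the other 23 did not pass over all genes; adjusted over the list alone, 6 were lower and 0 higher. CXCL8, the interleukin-8 gene, had a log2 ratio of -0.95 ± 0.15, IL1B -1.33 ± 0.26 and CXCL2 -0.95 ± 0.20, each lower in 5 of 5 lines. The camera adjusted p was 3.7e-07 with the preset correlation, but the adjusted p = 0.17 with an estimated correlation.

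Genes of the cornified envelope and keratinocyte differentiation were shifted down as well, with a mean log2 ratio of -0.40 over 42 measured members and a camera adjusted p of 3.4e-05, against an adjusted p = 0.17 with an estimated correlation. CSTA fell and 41 did not pass over all genes; adjusted over the list alone, 7 were lower and 1 higher. SLPI, a secreted protease inhibitor gene, had a log2 ratio of -0.88 ± 0.16, and SERPINB3 -1.16 ± 0.27. The list's median was -0.64 in SCC-1, where 18 members were at least 2-fold lower, and -0.01 in SCC-012.

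Among genes reported in the literature as p63 targets, 0 of 46 measured passed over all genes; adjusted over the list alone, 10 were lower and 1 higher. HK2, the hexokinase gene, had a log2 ratio of -0.74 ± 0.11, HAS3, a hyaluronan synthase gene, -1.41 ± 0.24, FAT2, a protocadherin gene, -1.26 ± 0.23, and JAG1, a Notch ligand gene, -0.76 ± 0.14. The camera adjusted p was 0.0044 (mean log2 ratio -0.19), with an adjusted p = 0.17 with an estimated correlation. HK2 is also in the hypoxia list, FAT2 in the desmosome list and JAG1 in the Notch list. The list of targets came from general knowledge, and whether any entry goes back to these samples was not checked.

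Of the Notch pathway, 0 of 21 measured genes passed over all genes and 5 were lower adjusted over the list alone, among them HES2 (log2 -1.49 ± 0.27), JAG1 and DLL1 (-1.09 ± 0.32). The list's camera adjusted p was 0.0022, and the adjusted p = 0.17 with an estimated correlation. In the EGF receptor family and its ligands, 0 of 13 passed over all genes and 1 was lower adjusted over the list alone, the ligand gene HBEGF (-1.15 ± 0.19), with a camera adjusted p of 0.012 and an adjusted p = 0.17 with an estimated correlation.

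The next list joined stress genes with immediate early genes, and the latter respond within minutes to growth signals. It had 0 of 39 passing over all genes and 9 lower and 1 higher adjusted over the list alone. IER3 had a log2 ratio of -0.52 ± 0.07, JUNB -0.51 ± 0.09 and DUSP6, an ERK phosphatase gene, -1.05 ± 0.20. The camera adjusted p was 0.0022, and the adjusted p = 0.17 with an estimated correlation, and the call was lost in the A and B lines. Of the hypoxia and glycolysis list, 0 of 23 passed over all genes and 5 were lower adjusted over the list alone, among them VEGFA (-1.11 ± 0.24) and NDRG1 (-0.83 ± 0.22). Its camera adjusted p was 0.013, with an adjusted p = 0.23 with an estimated correlation, and the call was lost without SCC-012 and in the A and B lines.

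Of 26 desmosome and cell junction genes, 0 passed over all genes and 3 were lower adjusted over the list alone, namely FAT2, DSG3, the desmoglein 3 gene (log2 -0.60 ± 0.14), and NECTIN1 (-0.54 ± 0.13). The camera adjusted p was 0.013, the adjusted p = 0.17 with an estimated correlation, and the call was lost without HaCaT and in the A and B lines. In the hemidesmosome and basement membrane list, 0 of 20 passed over all genes, and adjusted over the list alone FRAS1 was higher (0.81 ± 0.15) and ITGA6, the integrin alpha 6 gene, lower (-0.49 ± 0.10). As a set it did not pass (camera adjusted p = 0.76), and its mean of 0.02 and its median of -0.01 differed in sign. Basal keratins and basal keratinocyte markers did not pass as a set (camera adjusted p = 0.076, and the adjusted p = 0.37 with an estimated correlation), with 0 of 14 over all genes and 2 lower adjusted over the list alone, S100A2 (-0.82 ± 0.17) and FGFBP1 (-0.63 ± 0.18). With the preset correlation the list passed under quantile normalization (camera adjusted p = 0.029), with the mean of all probe sets (0.022), without HaCaT RG (0.021), without SCC-012 (0.025) and without the pairing as a block (0.022).

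Interferon response genes were shifted up over the 5 lines, with a mean log2 ratio of 0.38 over 44 measured members and a camera adjusted p of 2.8e-10. With an estimated correlation of 0.52 between members the adjusted p = 0.28 with an estimated correlation. None of the 44 passed in limma over all genes and 8 were higher adjusted over the list alone, among them MX2 (log2 0.69 ± 0.15), IFI6 (0.87 ± 0.19) and IFIT1 (0.95 ± 0.25), each higher in 5 of 5 lines. The list's median log2 ratio was 1.13 in SCC-6, where 24 members were at least 2-fold higher, 0.41 in SCC-1, 0.25 in HaCaT RG, 0.06 in HaCaT and 0.00 in SCC-012. Without SCC-6 the list's mean was 0.19, with a camera adjusted p of 0.00014 and an adjusted p = 0.39 with an estimated correlation.

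Mesenchymal markers were shifted up, with a mean of 0.28 over 40 measured members, a camera adjusted p of 0.00024 and an adjusted p = 0.17 with an estimated correlation. Of these 0 passed over all genes and 3 were higher adjusted over the list alone, FSTL1 (log2 0.52 ± 0.12), FBN1, the fibrillin 1 gene (1.28 ± 0.29), and COL5A1, a collagen gene (1.04 ± 0.26). The list's median was -0.11 in SCC-012 and between 0.04 and 0.34 in the other lines. Of 31 neural markers L1CAM rose and 30 did not pass over all genes; adjusted over the list alone 2 were higher, L1CAM and SEMA3C (0.83 ± 0.21). The camera adjusted p was 0.021, with an adjusted p = 0.30 with an estimated correlation. The call was lost without HaCaT RG (camera adjusted p = 0.19), with no filter (0.13), with the mean of all probe sets (0.058), with the HaCaT lines averaged (0.068), in the Plus 2.0 lines (0.20) and without the pairing as a block (0.068). The invasion and metastasis list, which also holds L1CAM, S100P and CXCL8, did not pass as a set (camera adjusted p = 0.42); 1 of its 52 measured genes rose and 1 fell over all genes, and 2 were higher and 5 lower adjusted over the list alone.

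**Figure D2:**
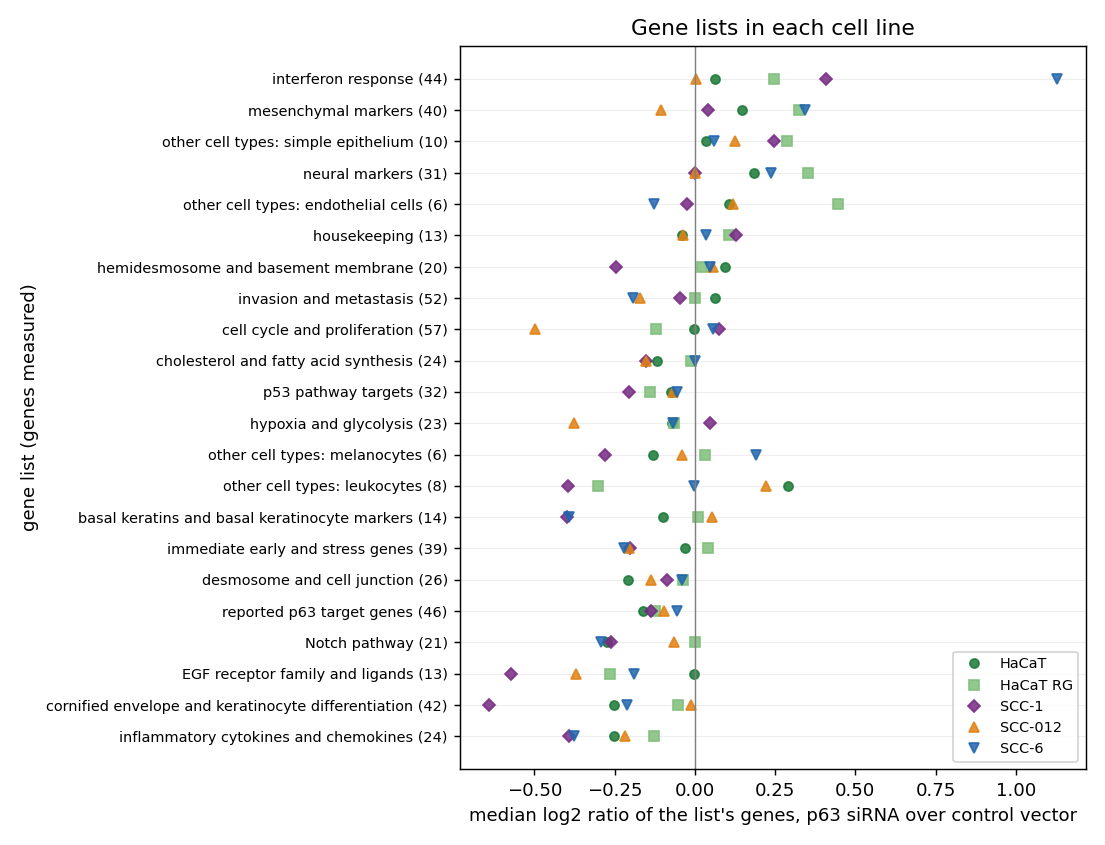
Median log2 ratio of p63 siRNA over control vector (horizontal axis) of each of 22 gene lists (vertical axis, with the number of genes measured), with 1 symbol per cell line. The interferon response list reached 1.13 in SCC-6, and the cell cycle list -0.50 in SCC-012.

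Of 57 cell cycle and proliferation genes 0 passed over all genes and 0 adjusted over the list alone. PTTG1, the securin gene, had a log2 ratio of -0.32 ± 0.09 and RFC4 -0.28 ± 0.08, both lower in 5 of 5 lines. The set was shifted down (camera adjusted p = 0.0044, and the adjusted p = 0.59 with an estimated correlation), with a median of -0.50 in SCC-012 and between -0.12 and 0.08 elsewhere. The call was lost without SCC-012, where the list's mean was 0.0053 (camera adjusted p = 0.82), and in the A and B lines, where it was 0.0049 (0.81). Targets of the p53 pathway were shifted down (mean -0.11, camera adjusted p = 0.025, and the adjusted p = 0.17 with an estimated correlation), a call lost without SCC-1, in the Plus 2.0 lines and in the A and B lines. Of 32 measured, 0 passed over all genes, and adjusted over the list alone 4 were lower and 1 higher, with MDM2 at -0.52 ± 0.11 and TP53I3 at 0.63 ± 0.13. Cholesterol and fatty acid synthesis genes were shifted down (mean -0.10, camera adjusted p = 0.013, and the adjusted p = 0.17 with an estimated correlation), with 0 of 24 passing over all genes and ELOVL6 (-0.52 ± 0.11) and STARD4 (-0.58 ± 0.13) lower adjusted over the list alone. That call was lost in the lines of either array type and without the pairing as a block.

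Markers of other cell types were tested in the same way. Simple epithelium markers were shifted up (mean 0.20, camera adjusted p = 0.026, and the adjusted p = 0.17 with an estimated correlation), a call lost without HaCaT RG, without SCC-1 and in the Plus 2.0 lines. KRT8 and KRT18, keratin genes of simple epithelia, had log2 ratios of 0.31 ± 0.13 and 0.25 ± 0.10, with 0 of 10 members passing over all genes or adjusted over the list alone. Leukocyte (camera adjusted p = 0.72, 8 genes), endothelial (0.44, 6 genes) and melanocyte markers (0.60, 6 genes) and 13 housekeeping genes (0.26) did not pass, and 0 of their members passed over all genes or adjusted over the list alone.

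In all, 15 of the 22 lists passed in camera with the preset correlation of 0.01, 4 higher and 11 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.17. The estimated correlation was under 0.01 for p63 targets (-0.013), EGF receptor (-0.024), simple epithelium (-0.019), p53 targets (0.00064) and desmosome (0.0090). For p63 targets the unadjusted camera p still rose from 0.0016 to 0.019. A higher correlation does not account for the calls lost by these lists. With an estimated correlation camera takes its p from the 4 residual degrees of freedom, and with the preset one from the far larger number of genes. A call lost with an estimated correlation thus does not by itself show that a list's members are correlated. With fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 3 passed: inflammatory cytokines and chemokines, reported p63 targets, and the EGF receptor family.

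The design text of the series speaks of transformed and non-transformed cells without saying which lines are which, and the response was compared between HaCaT and HaCaT RG and the 3 SCC lines. TNFSF15, a TNF-family cytokine gene, had mean log2 ratios of 1.45 in the HaCaT lines and -0.36 in the SCC lines, a difference of -1.81 ± 0.22 (SE), with an adjusted p of 0.29 by limma. SERPINB7 had means of 0.01 and -1.69, and CRABP2, a retinoic acid-binding protein gene, 0.09 and -1.18. In the other direction FGFR3, a fibroblast growth factor receptor gene, had means of -1.88 in the HaCaT lines and 1.35 in the SCC lines, and HDC, the histidine decarboxylase gene, -1.22 and 1.07, each with an adjusted p of 0.98 by limma. In limma 0 genes passed, and no other tool was run. At an unadjusted p under 0.05 limma gave 612 genes, fewer than the 707.2 expected without any effect. HaCaT and SCC ratios did not overlap for 2725 genes (19.3%), where chance gives 20% for 2 lines against 3.

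Within a line there was 1 sample per vector, so these ratios have no replicate check. The number of genes at least 2-fold apart was 509 in HaCaT, 1055 in HaCaT RG, 1106 in SCC-1, 872 in SCC-012 and 922 in SCC-6, and with genes of mean signal of at least 250 these counts were 188, 478, 489, 382 and 364. Among genes with a signal of at least 500 in the brighter sample, GNAO1 went from 1093 to 121 in HaCaT, and BMP4, a bone morphogenetic protein gene, from 268 to 1020. In HaCaT RG, S100A7, the psoriasin gene, went from 6375 to 434 and FLG, the filaggrin gene, from 77.4 to 500.4. In SCC-1, KRT4, a keratin of mucosal epithelia, was at least 13.8-fold lower, its p63 siRNA signal lying at the floor, and FYB2 at least 11.3-fold higher. In SCC-012, WNT11 was at least 17.9-fold higher, SOSTDC1 went from 323 to 3720, and PTK6 from 583 to 57.0. In SCC-6, ITGB5, an integrin gene, went from 350.8 to 3585, IFI44L from 328 to 2375 and GPX2 from 1058 to 162. With a floor of 100 the log2 ratio went from 4.17 to 3.17 for WNT11, from -3.35 to -2.54 for PTK6, from -3.79 to -2.79 for KRT4, from 3.50 to 2.50 for FYB2 and from 2.69 to 2.32 for FLG. Averaging all probe sets of the gene brought the log2 ratio of GNAO1 from -3.17 to -0.40, that of KRT4 from -3.79 to -1.89, that of FYB2 from 3.50 to 1.97, that of GPX2 from -2.71 to -1.70 and that of ITGB5 from 3.35 to 0.88.

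The log2 ratios of different lines were weakly correlated across the 14144 genes, which are not independent replicates. Pearson's r over the 10 pairs of lines averaged 0.106 ± 0.028 (SD), from 0.067 for HaCaT RG with SCC-012 to 0.146 for HaCaT with SCC-6, and Spearman's rho ran from 0.071 to 0.182. With genes of mean signal of at least 250 the average r was 0.169. The only repeat measurement was given by 100 probe sets found on both HG133A and HG133B, whose log2 ratios differed with an SD of 0.296 in HaCaT RG and 0.190 in SCC-1. The ratios themselves had SDs of 0.244 on A and 0.242 on B in HaCaT RG, and 0.160 and 0.175 in SCC-1. Their Pearson's r between A and B was 0.26 in HaCaT RG and 0.36 in SCC-1. Over all genes tested the ratios had an SD of 0.569 in HaCaT RG and 0.574 in SCC-1. The shared probe sets moved less than that, which keeps r low, so this r does not show how well the arrays agree for other genes. A floor of 100 left the values of the shared probe sets unchanged, so they do not speak for dim genes.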

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

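The tests of the gene and 1.5-fold counts against other splits were chosen after the results were seen. So were the tests of an equal effect and of the vector in the interferon pattern, and of the correlation between lines. The same holds for the list test between HaCaT and SCC and the genes found on Plus 2.0 alone. For the interferon list without SCC-6, the fit with the preset correlation was planned and that with an estimated correlation was added later.

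The interferon response list differed between line types in camera on the difference of the ratios (adjusted p = 0.011, median 0.14 in the HaCaT lines and 0.46 in the SCC lines, and an adjusted p = 0.78 with an estimated correlation). The lines did not part by type: the median was 1.13 in SCC-6 and 0.41 in SCC-1 but 0.00 in SCC-012, under those of HaCaT (0.06) and HaCaT RG (0.25). Array scaling is argued against, since the list's median in SCC-6 was 1.01 with the medians set equal and 1.11 with quantile normalization, against 1.13; the deposited values already have the scale used here. An effect of equal size in all lines could not be excluded: the mean over 44 genes in SCC-6 exceeded that in HaCaT by 1.10, and by 0.904 after taking off 2 standard errors over genes, but with 1 pair per line this error holds no spread between cultures. The siRNA vector and the loss of its target cannot be told apart, since there was 1 siRNA arm per line. Without SCC-6 the list's mean went from 0.38 to 0.19, with a camera adjusted p of 0.00014 with the preset correlation and an adjusted p = 0.39 with an estimated correlation, and a response of only some lines, which may be biological, stays an untested hypothesis.

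The ratios of different lines correlated weakly (mean r = 0.106). Noise of dim probe sets may account for part of it: the mean r was 0.035 in the 3536 dimmest genes and 0.280 in the 3536 brightest, 7.99 times as high. Array type is argued against as the main account, since pairs of lines on the same array type correlated by 0.011 more than the others, less than the highest of the 10 choices of 2 lines (0.021). A smaller part of array type cannot be excluded, since 10 choices are few and bright genes were not compared apart. Differences between the lines themselves stay open.

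For the 6 genes called by limma, 5 of 100 splits drawn from the 126 possible gave as many, the real one included, and the highest other gave 6. The 4 others parted 1 pair only, while the fit pairs samples by cell line, and each gave 6 genes and 3 lists. In this fit, splits that part the same 1 pair are the same comparison, so the 100 splits are not 100 separate groupings. Among the 16 splits that part all 5 pairs, too few for a share under 0.05, the highest other gave 1. For the 15 lists 1 of 100 splits gave as many and the highest other gave 13, a split that parts 3 pairs. The planned bound of 5% on this share was wrong for a paired fit, since most of the 100 splits break pairs that it blocks on; among the 16 that part all 5 pairs, too few for a share under 0.05, the highest other gave 9. For the 22 genes moved 1.5-fold in all lines, 1 of 16 sign patterns gave as many and the highest other gave 7, and 16 patterns are too few for a share under 0.05.

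Immediate early and stress genes also differed between line types in camera (adjusted p = 0.039, median 0.03 in the HaCaT lines and -0.29 in the SCC lines, and an adjusted p = 0.59 with an estimated correlation). By Dixon's rule (critical value 0.71 for 5 values), 5 of 42 sets of 5 values held a line far from the other 4. A rate of 1 in 20 gives 2.1, which holds for independent sets. The genes were chosen for 1 direction in all lines and the lists share members, so 2.1 is a rough guide only. PSG7 had a log2 ratio of 1.87 in HaCaT RG and between 0.63 and 0.84 elsewhere. In SCC-012 CSTA stood at -0.52, against -2.36 to -2.02 in the other lines, and S100P at -1.32, against -0.89 to -0.80. The hemidesmosome list's median was -0.25 in SCC-1 and 0.02 to 0.10 elsewhere, and that of the hypoxia list was -0.38 in SCC-012 and -0.07 to 0.05 elsewhere. Among 1062 genes measured on Plus 2.0 alone, 4 were at least 2-fold apart the same way in its 3 lines, KRTAP11-1 lower and UNC13C, LINC00052 and LINC01121 higher, and the highest of the other 3 sign patterns gave 3.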

How the results depend on the processing

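The fit without a filter that leaves out genes at the floor was chosen after the results were seen. Causes were not tested unless given. The 6 genes called across lines became 0 with no filter (2 once the 568 genes at the floor in all samples were left out), 3 with the mean of all probe sets, 2 without an eBayes trend, 2 with the HaCaT lines averaged, 0 in the 3 Plus 2.0 lines and 0 in the 2 A and B lines (fewer samples; 1454 and 787 by limma at an unadjusted p under 0.05, against 707.2 expected without any effect), 14 probe sets when each was tested, and 0 without the pairing as a block. Leaving out 1 line gave 2 to 7: 2 without HaCaT, HaCaT RG or SCC-6, 3 without SCC-1 and 7 without SCC-012. Over 19 settings LINC01503 was called in 15, IL1A in 14, S100P in 9, L1CAM and SAT1 in 8 and CSTA in 7, and none of the 6 with no filter, in the subsets by array type or without the block.

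The 22 genes moved 1.5-fold became 12 with a floor of 100, 38 with the HaCaT lines averaged, 104 in the 3 lines, 564 in the 2 lines and 38 to 53 without 1 line, as fewer ratios must pass. The 15 lists became 11 in the 3 Plus 2.0 lines, without neural, p53, cholesterol and simple epithelium, 9 in the 2 A and B lines, without desmosome, p53, cell cycle, immediate early, cholesterol and hypoxia, 0 with an estimated correlation and 3 with fry; without the pairing as a block the neural and cholesterol lists lost their call, basal keratins gained one, and no other list's call changed. The neural list also lost it with no filter, with the mean of all probe sets, with the HaCaT lines averaged and without HaCaT RG. Basal keratins also gained it with quantile normalization, with the mean of all probe sets, without HaCaT RG and without SCC-012. A floor of 100 gave 205 genes at least 2-fold apart in HaCaT, 557 in SCC-012 and 576 in SCC-6, and a mean signal of at least 250 gave 188, 478, 489, 382 and 364 in HaCaT, HaCaT RG, SCC-1, SCC-012 and SCC-6 and a mean r of 0.169. With both HaCaT lines in the fit, HaCaT against SCC gave 0 genes in limma in each setting run, with 462 to 704 at an unadjusted p under 0.05. The main fit gave 612, fewer than the 707.2 expected without any effect. Leaving out a HaCaT line leaves 1 in its group, so those counts are not given.

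The sign of the mean or of the test turned for the melanocyte list (0.067 at a mean signal of at least 250), the hemidesmosome list (-0.018 at a mean signal of at least 250, -0.0068 with the mean of probe sets, -0.065 in the A and B lines, and -0.0045 to 0.080 without 1 line), the leukocyte list (0.10 in the Plus 2.0 lines, -0.317 to -0.00092 without 1 line, where its test turned without HaCaT RG), the housekeeping list (-0.0069 with quantile normalization, -0.0095 in the Plus 2.0 lines), the endothelial list (-0.0056 with the mean of probe sets, -0.050 in the Plus 2.0 lines, -0.013 without HaCaT RG) and the cell cycle list (0.0049 in the A and B lines, -0.149 to 0.0053 without 1 line, the latter without SCC-012). They turned for PECAM1 (-0.017 with the mean of probe sets, -0.090 in the A and B lines), HLA-DRA (0.39 in the Plus 2.0 lines, -1.07 to 0.056 without 1 line, the latter without HaCaT RG), MS4A1 (-0.00044 in the A and B lines) and ARSD between HaCaT and SCC (-0.015 with the mean of probe sets). Signal over background limits dim genes. The planned check of the targeted gene, with its alternatives, was not run.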

Other observations

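The 2 hypotheses here were formed after the results were seen and tested on list members not seen before.

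Contractile and actin-binding genes were looked at because MYL9 and TAGLN were higher in 5 of 5 lines. TPM1, a tropomyosin gene, had a log2 ratio of 0.83 ± 0.15 and was higher in 5 of 5 lines, with an adjusted p of 0.095 by limma, and CALD1, the caldesmon gene, had 0.49 ± 0.17, while VCL, the vinculin gene, had -0.10 ± 0.08 and ACTA2 -0.23 ± 0.20. Over 8 members not seen before, the camera p was 0.0062 and p = 0.047 with an estimated correlation, and the list's median was 0.22 in HaCaT, 0.28 in HaCaT RG, 0.14 in SCC-1, -0.07 in SCC-012 and 0.23 in SCC-6. The median passed 0.2 in 3 lines, fewer than the 4 the hypothesis required, so a rise of contractile genes with p63 siRNA may hold in part of the lines and stays undecided.

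ERK pathway output genes were looked at because DUSP6 and SPRY2 were lower in 5 of 5 lines. Over 6 members not seen before the camera p was 0.27 (p = 0.60 with an estimated correlation), and the median passed -0.2 in 2 lines, SCC-012 (-1.31) and SCC-6 (-0.39), and was 0.21 in HaCaT and 0.10 in HaCaT RG. The hypothesis of a lower ERK output across lines was not borne out.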
